A study of Peromyscus maniculatus with 6 samples.

How the data were processed

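RNA was measured in primary fibroblasts grown from ear punches of 3 deer mice (Peromyscus maniculatus, BW stock), with 1 control and 1 tunicamycin library from each animal, 6 libraries in all. Per the labels' protocols, cells were plated at 300000 per well for 24 h, treated with tunicamycin for 5 h and lysed at once. The label gives the tunicamycin concentration as 5 mg per mL, and that value could not be checked here. The vehicle given to control wells is not given in the sources used here. Per the labels, libraries were directional (they keep the strand of the RNA) and were sequenced in paired-end mode across 3 lanes.

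The table deposited by the authors holds whole-number read counts per gene, not normalised, with 1 column per library. Reads were aligned with STAR 2.6.1 and handled with SAMtools 1.6, and genes were counted with featureCounts of the Subread package, per the submitters' processing notes. The genome build, the annotation release, and the treatment of reads that map to several places are not given in the sources used here. The deposited table is titled as strand-specific, which is the only statement on how the authors' counting used strand. It gives Ensembl gene IDs with the scaffold, exon bounds and strand of each gene, and coordinates are printed as the table gives them. It lists 24281 genes, of which 6252 have an ID and no name. Counts on unnamed IDs made up 22.1 to 26.1% of each library. Gene names were taken from the table alone, because the gene table supplied with the reference belongs to another assembly and holds none of these IDs. There are 137 names that sit on more than 1 ID, and no gene named under the rule below is among them. Xbp1 and Herpud1, which that rule includes, are not named in the table and are not reported.

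Libraries held 37852385 to 49352126 counts on genes. No library was a copy of another, since the chi-square per degree of freedom between pairs of libraries lay between 34.0 and 309.6. At this depth counting error is small for genes well above 1 CPM (counts scaled to library size). Replicates are animals, so p-values measure the spread between 3 animals' cultures.

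Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13503 genes, 10509 of them named. Library sizes were scaled by TMM (trimmed mean of M values). The quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) compared the 3 tunicamycin with the 3 control libraries, with no other term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. A gene is said to have risen, fallen or changed only if it passed that threshold. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. CPM values are TMM-normalised and given as mean ± SD over 3 libraries. A difference within a pair is the difference of log2 CPM with a prior count of 2.

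The numbers in the sample titles name the animal, so control and tunicamycin libraries with the same number are a pair. Deviations from the group means correlated at 0.66, 0.41 and 0.22 across genes (not independent replicates) within the pairs of animals BW35770, BW35772 and BW35773. A fit with the animal as a block (the replicate block) was therefore run beside the main one, and its value is printed where it changes a call or moves a count by more than 1.5 times.

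The gene lists, the rule for named genes, the main test and most alternatives were fixed before the data were examined. There were 28 lists, for the unfolded protein response, other pathways, and markers of fibroblasts and other cells of the ear. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 26 lists with at least 5 tested members. Camera was repeated with an estimated correlation, and fry was run as a test of whether a list's own genes moved one way. With an estimated correlation camera uses the residual degrees of freedom (4 without the block, 2 with it), which leaves it little power here. Named genes are the 6 largest rises and 6 largest falls among called, named genes with a mean log2 CPM of at least 1 that went the same way in all 3 pairs, 10 fixed response genes, and the 2 smallest p-values of each pathway list. This rule gave 52 genes, of which 29 were higher, 8 lower and 15 not called. Other genes named in the text were chosen after their values were seen.

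Alternatives were other scalings, filters and tools (DESeq2 1.42.0 and limma-voom), a fold change of 1.5 as the null hypothesis, and leaving out each library or animal. Fits without a single library had no block, so differences between animals counted as error in them. Removal of each library's trend with exon length (a lowess curve entered as edgeR offsets) was added after seeing the data. Exon length is the sum of annotated exon bases in the table.

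The steps were tested on simulated counts for the control and tunicamycin comparison with 3 libraries each, 13345 tested genes and 196 changed genes. The fit without the block recovered 0% of genes changed 1.5-fold, 32.3% of those changed 2-fold and 92.3% of those changed 4-fold, with 0% false calls. The blocked fit recovered 10.6, 64.6 and 93.8%, and 6.8% of its calls were false. DESeq2 with the block had 17% false calls. The simulation drew animal effects for each gene on its own (SD 0.22 on the log2 scale). It gave all animals the same treatment effect and no trend with exon length. The real libraries differ in these respects, so the rates may not hold for them. Figures were drawn with matplotlib 3.10.9.

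The spans of Stx5a, Hspa8 and Mcm7 hold small genes on the same strand, and those of Txndc11, Syvn1 and Sdhd overlap a gene on the other strand. Values of genes with near-identical copies, such as those of ribosomal proteins, Hspa8 and the Cyp1a pair, are uncertain to the extent that the counting split or dropped shared reads.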

Results

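The series measured the whole transcriptome of deer mouse ear fibroblasts after the unfolded protein response was induced with tunicamycin. Tunicamycin blocks the first step of N-linked glycosylation, so that unglycosylated proteins accumulate in the endoplasmic reticulum (ER). Cultures from 3 animals, BW35770, BW35772 and BW35773, each gave 1 control library and 1 library treated for 5 h. Control libraries held 43367273, 37852385 and 40051429 counts on genes and tunicamycin libraries 44056273, 49352126 and 40698179, in the same order of animals.

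After 5 h of tunicamycin 23 of 28 targets of the PERK-ATF4-CHOP arm of the unfolded protein response had risen, with 13 of 28 genes of amino acid uptake and tRNA charging, 9 of 29 inflammatory genes and 8 of 34 immediate early genes. Of 19 cytosolic heat shock genes 5 fell. In all, 241 genes rose and 107 fell among 13503 tested (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 animals). Of these, 139 rose and 61 fell by at least 2-fold. Of the called genes, 35 that rose and 18 that fell have no name in the deposited table. Every called gene went the same way in all 3 pairs. With the animal as a block, 415 genes rose and 324 fell, and these included all 241 and all 107. The counts moved with each library left out. Genes that rose numbered 79, 51 and 46 without the control of animal BW35770, BW35772 or BW35773, and 97, 170 and 313 without the matching tunicamycin library. Genes that fell numbered 34, 15 and 19 without those controls, and 37, 60 and 251 without those tunicamycin libraries. In a principal component analysis the treated library of animal BW35772 lay at 52.4 on the first component (33.9% of the variance), with the others between -46.7 and 14.6, and that of BW35773 at 51.3 on the third component (21.4%), with the others between -21 and 4.3. From control to treated, animals BW35770, BW35772 and BW35773 went from 1.6 to -45.1, 31.1 to -30.7 and 30 to 13 on the second component (29.5%). On the third they went from -21 to 4.3, -20.6 to -10.2 and -3.8 to 51.3. Both components thus moved the same way in all 3 pairs. The SD of log2 differences over genes was 0.59, 0.70 and 0.60 in animals BW35770, BW35772 and BW35773. Across genes, which are not independent replicates, log2 differences correlated at r = 0.56 between animals BW35770 and BW35772, 0.32 between BW35770 and BW35773, and 0.14 between BW35772 and BW35773.

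The largest rise was that of Cyp1a1, a cytochrome P450 best known as a target of the aryl hydrocarbon receptor (ENSPEMG00000015335, scaffold KI615330.1, bases 7070067 to 7076170, 7 exons). It went from 4.33 ± 3.28 to 330.1 ± 81.2 CPM (SD, n = 3), a log2 fold change of 6.24 ± 0.57 (SE, edgeR adjusted p = 0.00221), and of 7.07 without the control of animal BW35770. Its counts may include reads shared with Cyp1a2, which held 114 counts over the treated libraries against 44411 for Cyp1a1. Chac1, a glutathione-degrading enzyme, rose by 4.66 ± 0.14 on the log2 scale, from 6.75 ± 0.75 to 170.4 ± 10.9 CPM (edgeR adjusted p = 1.57e-05). Trib3, a pseudokinase that restrains ATF4 and CHOP, rose by 4.54 ± 0.14 (edgeR adjusted p = 1.57e-05). Fgf21, a stress-induced hormone, rose by 4.52 ± 0.61 from a low level of 0.37 ± 0.32 CPM. Its call was lost without the control of animal BW35770 (adjusted p = 0.053) or BW35773 (0.076), and its log2 fold change was 5.54 without that of BW35772. Ddit3, which encodes the transcription factor CHOP, rose by 3.95 ± 0.23, and Akap3, an anchoring protein for protein kinase A, by 3.42 ± 0.25. Among the falls, G0s2, an inhibitor of lipolysis, dropped from 26.3 ± 2.78 to 3.35 ± 0.60 CPM, a log2 fold change of -2.98 ± 0.20 (edgeR adjusted p = 0.000674). Id1 and Id2, inhibitors of basic helix-loop-helix factors, changed by -2.48 ± 0.32 and -2.21 ± 0.27. Scara3, a scavenger receptor, changed by -2.39 ± 0.31. The homeobox gene Dlx1 changed by -2.26 ± 0.28, and Sp7, the osteoblast factor osterix, by -2.10 ± 0.40 (edgeR adjusted p = 0.0407). Calls were lost for Id1 without the control of BW35773 (edgeR adjusted p = 0.064), for Scara3 without that of BW35772 (0.053) and for Dlx1 without either of these controls (0.071 each). The call for Sp7 was lost without the control of BW35772 or BW35773 (0.18 and 0.17) or the tunicamycin library of BW35770, BW35772 or BW35773 (0.092, 0.084 and 0.064). These fits did not pair the animals, whose control levels of Sp7 ran from 61.5 to 143.8 CPM. With the replicate block and all libraries the edgeR adjusted p was 0.00099 for Fgf21 and 0.00023 for Id1 and for Sp7. It was 0.00016 for Scara3 and 0.0068 for Dlx1. Differences within the pairs were -2.07, -2.19 and -2.02 for Sp7.

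**Figure D1:**
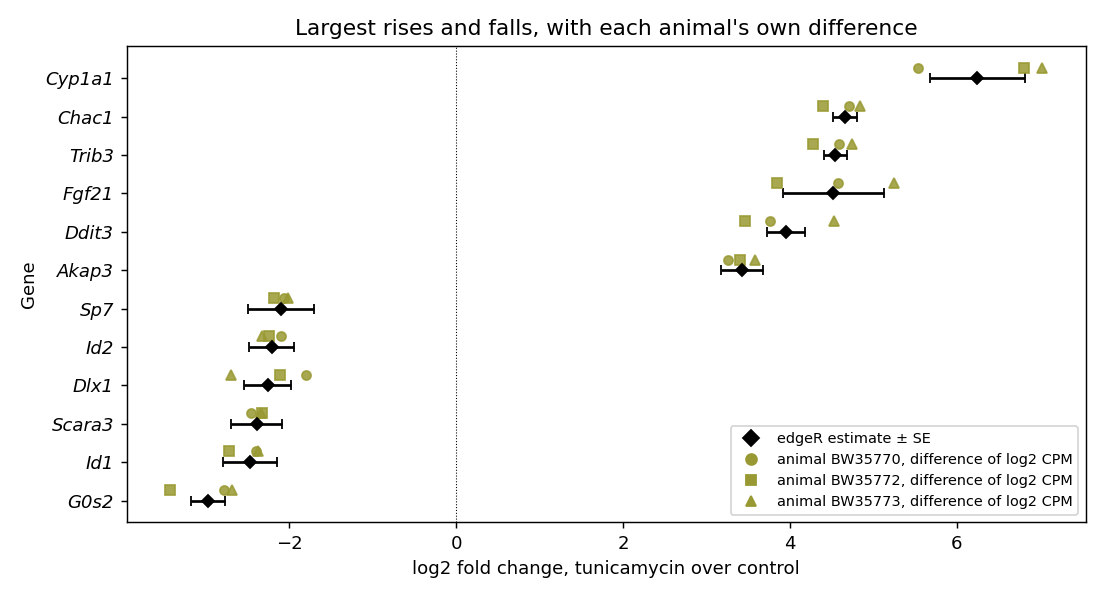
Log2 fold change of tunicamycin over control (horizontal axis) for the 6 largest rises and 6 largest falls (vertical axis). Diamonds are edgeR estimates with SE over 3 animals, and other symbols are each animal's own difference of log2 CPM, which for Cyp1a1 were 5.54, 6.81 and 7.02.

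Targets of PERK, ATF4 and CHOP, the arm that lowers translation and induces amino acid genes, formed the list with the largest shift. Of 28 tested members 23 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 fold change of 1.63. Atf4 itself went from 187.1 ± 23.2 to 1036 ± 107 CPM, a log2 fold change of 2.47 ± 0.15 (edgeR adjusted p = 0.000507). Asns, asparagine synthetase, rose by 1.41 ± 0.11. Slc7a5, a transporter of large neutral amino acids, rose by 3.36 ± 0.15, from 48.2 ± 4.41 to 493.5 ± 65.2 CPM. The list stood above other genes in camera (adjusted p = 1.7e-33), and the call was lost, with an adjusted p = 0.059 with an estimated correlation, and 0.61 with an estimated correlation and the replicate block. Of the 11 lists called by camera, 0 held with an estimated correlation. In these 11 lists the estimated correlation ran from 0.046 (immediate early genes) to 0.823 (electron transport genes), above the preset 0.01. It was 0.113 for PERK-ATF4-CHOP targets and 0.33 for ER chaperones. Camera p-values at the preset may therefore be too small. The version with an estimated correlation also rests on 4 residual degrees of freedom, or 2 with the block, which leaves it little power. A call lost there can come from either, and these were not told apart.

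**Figure D2:**
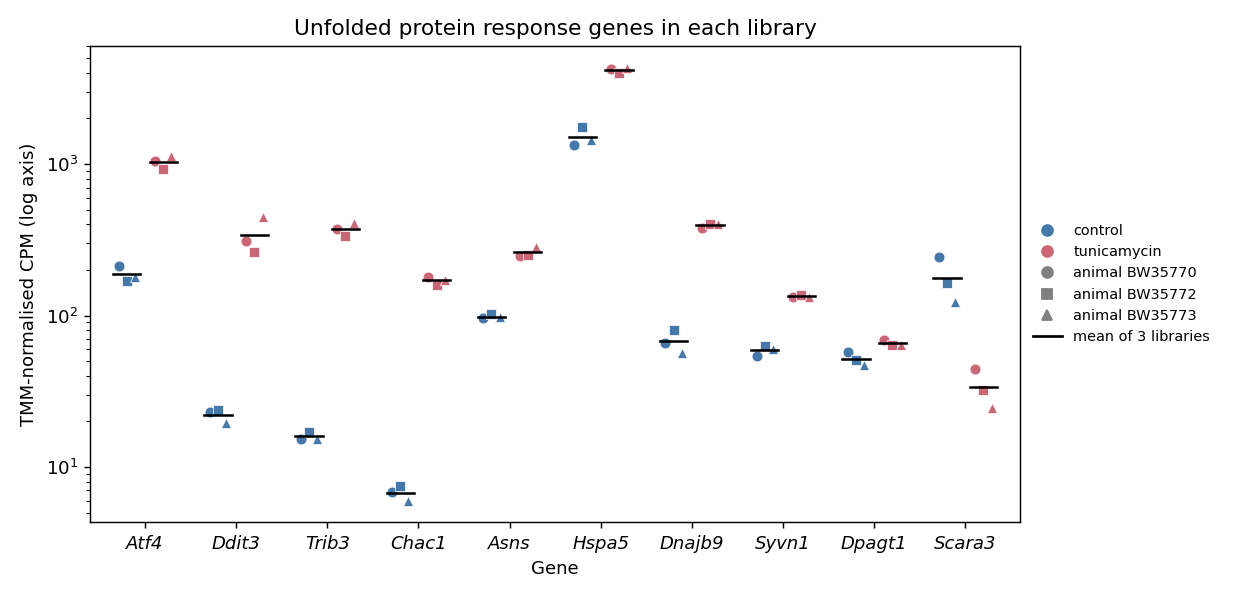
TMM-normalised CPM on a log axis (vertical) of 10 genes of the unfolded protein response (horizontal) in each of 6 libraries, with symbols for animals, colours for treatment and bars for the mean of 3 libraries. Treated libraries lie above all controls for Atf4, Ddit3, Trib3, Chac1, Asns, Hspa5, Dnajb9, Syvn1 and Dpagt1 (not called), and below them for Scara3.

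Among ER chaperones and folding enzymes, of 30 tested members 6 rose and 0 fell (8 and 0 adjusted over the list alone), and the median log2 fold change was 0.18. Hspa5, the main ER chaperone BiP, went from 1510 ± 223 to 4189 ± 183 CPM, a log2 fold change of 1.47 ± 0.16 (edgeR adjusted p = 0.00512). Txndc11, a thioredoxin-domain protein of the ER, rose by 0.91 ± 0.12. Manf, a secreted ER stress protein, rose by 1.79 ± 0.23, while Calr, the chaperone calreticulin, had a log2 fold change of 0.18 ± 0.16 and was not called. Hsp90b1 and Sdf2l1 were also called higher with the replicate block. Camera called the list higher (adjusted p = 0.00021), with an adjusted p = 0.46 with an estimated correlation and 0.09 with fry. Without both libraries of animal BW35773 the camera adjusted p was 0.064. The call for Hspa5 was lost without the control of BW35773 (edgeR adjusted p = 0.056), and that for Txndc11 without the control of BW35770, BW35772 or BW35773 (0.056, 0.052 and 0.093). These fits did not pair the animals. Pairing by the replicate block over all libraries gave edgeR adjusted p = 0.0023 for Hspa5 and 0.0097 for Txndc11. Without animal BW35770 the blocked values were 0.058 and 0.18.

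Most members of the IRE1-XBP1 list, which serve protein entry into the ER and secretion, were not called. Of 25 tested members 2 rose and 0 fell (2 and 1 adjusted over the list alone). Dnajb9, a co-chaperone of BiP, rose by 2.55 ± 0.15 on the log2 scale, from 67.5 ± 11.8 to 394.9 ± 14.1 CPM (edgeR adjusted p = 0.000488). Sec23b, a coat protein of ER vesicles, rose by 0.63 ± 0.12. In limma-voom the call for Sec23b was lost (adjusted p = 0.05, not under the threshold). With the replicate block 3 rose and 1 fell, Arfgap3 and Sec61g (a subunit of the translocon, log2 fold change -0.96) being added. In ER-associated degradation, the disposal of misfolded ER proteins, 2 of 31 members rose and 0 fell (2 and 0 adjusted over the list alone). These were Syvn1, the ubiquitin ligase HRD1, at 1.19 ± 0.11, and its partner Sel1l at 0.94 ± 0.19. Sel1l lost its call with upper-quartile factors (edgeR adjusted p = 0.056) and without the control of BW35770, BW35772 or BW35773 (0.13, 0.2 and 0.12) or their tunicamycin libraries (0.085, 0.095 and 0.062). Sec23b lost its call without those controls (0.17, 0.2 and 0.21) or those tunicamycin libraries (0.055, 0.082 and 0.052). These fits did not pair the animals. Pairing by the replicate block over all libraries gave edgeR adjusted p = 0.0102 for Sel1l and 0.0265 for Sec23b. Without animal BW35770 the blocked values were 0.16 and 0.23. Camera called both lists higher at an adjusted p = 0.04, and with an estimated correlation the adjusted p was 0.61 for the IRE1-XBP1 list and 0.46 for ER-associated degradation. Both calls were also lost with fry (adjusted p = 0.13 and 0.1) and in camera under the stricter filter (0.056 and 0.051). The IRE1-XBP1 call was lost without the control of animal BW35770 or BW35773 or the tunicamycin library of BW35772 or BW35773 (adjusted p = 0.096, 0.084, 0.058 and 0.41). The call for ER-associated degradation was lost without either library of animal BW35773 (adjusted p = 0.084 for the control and 0.33 for the treated library).

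In N-glycan synthesis and transfer, the pathway that tunicamycin inhibits, 3 of 41 members rose and 0 fell (6 and 3 adjusted over the list alone). Alg12, a mannosyltransferase, rose by 1.09 ± 0.12 on the log2 scale, Gmppb, which makes GDP-mannose, by 1.05 ± 0.19, and Alg2, another mannosyltransferase, by 0.68. Dpagt1, the enzyme tunicamycin binds, stood at 52.0 ± 5.16 CPM in controls and 65.8 ± 2.84 CPM with treatment, a log2 fold change of 0.34 ± 0.12 that was not called (edgeR adjusted p = 0.213). The list was not called (camera adjusted p = 0.52). Dolk and Alg14 fell with the replicate block, 2 members in all, and DESeq2 called 6 higher and 3 lower. Alg12 lost its call without the control of BW35773 (edgeR adjusted p = 0.05, not under the threshold). Gmppb lost its call without the control of BW35770, BW35772 or BW35773 (edgeR adjusted p = 0.067, 0.12 and 0.12) or their tunicamycin libraries (0.075, 0.08 and 0.061). These fits did not pair the animals. Pairing by the replicate block over all libraries gave edgeR adjusted p = 0.0042 for Alg12 and 0.0053 for Gmppb. Without animal BW35770 the blocked values were 0.077 and 0.098. Among known substrates of regulated IRE1-dependent decay (RIDD), the cleavage of ER-bound mRNA, 1 of 14 fell and 0 rose (1 and 0 adjusted over the list alone). That gene was Scara3, whose call was lost without the control of BW35772 in a fit without the block (edgeR adjusted p = 0.053). With the block and all libraries its edgeR adjusted p was 0.00016. Bloc1s1, a widely used reporter of this decay, had a log2 fold change of -0.33 ± 0.27 (edgeR adjusted p = 0.655). The RIDD list was not called (camera adjusted p = 0.07). With the replicate block it was called lower (camera adjusted p = 0.047, and adjusted p = 0.61 with an estimated correlation), 2 members fell, and the ganglioside synthase St3gal5 was called (log2 fold change -0.77 ± 0.13, edgeR adjusted p = 0.0193), as it was with DESeq2 (0.039).

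Of 28 aminoacyl-tRNA synthetases and amino acid transporters 13 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 fold change of 0.55. Cars, which charges cysteine tRNA, rose by 1.70 ± 0.14, and Slc7a11, the cystine transporter, by 2.19 ± 0.41. As drawn up, this list and the PERK-ATF4-CHOP list share Slc7a5, Slc7a11 and Slc3a2. The camera adjusted p was 8.4e-14, and the adjusted p was 0.1 with an estimated correlation. The call for Slc7a11 was lost without the control of BW35770, BW35772 or BW35773 (edgeR adjusted p = 0.14, 0.17 and 0.2) or the tunicamycin library of BW35772 or BW35773 (0.065 and 0.056), and in limma-voom (0.099). These fits did not pair the animals, and with the replicate block and all libraries its edgeR adjusted p was 0.0147.

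In the inflammatory and NF-kB list 9 of 29 members rose and 0 fell (16 and 1 adjusted over the list alone). Relb, an NF-kB subunit, rose by 1.37 ± 0.15 and Tnfaip3, a feedback inhibitor of NF-kB, by 1.78 ± 0.20 on the log2 scale. Among immediate early genes 8 of 34 rose and 0 fell (11 and 1 adjusted over the list alone). Myc went from 44.7 ± 4.12 to 202.1 ± 19.7 CPM, a log2 fold change of 2.18 ± 0.13 (edgeR adjusted p = 0.000488), and Egr1, a zinc-finger factor, rose by 2.63 ± 0.22. Camera adjusted p-values were 1.6e-10 for the inflammatory and 3.9e-06 for the immediate early list, and both lists had an adjusted p = 0.15 with an estimated correlation. With the replicate block 14 inflammatory genes rose and 1 (Cxcl12) fell, and of the immediate early genes 9 rose and 2 (Jun and Dusp1) fell. Tnfaip3 lost its call without the control of BW35772 (edgeR adjusted p = 0.06) in a fit without the block. With the block and all libraries its edgeR adjusted p was 0.0042.

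Of 19 tested cytosolic heat shock proteins 5 fell and 0 rose (12 and 0 adjusted over the list alone), and the median log2 fold change was -0.67. Hspa8, the constitutive HSC70 chaperone, went from 3336 ± 408 to 1052 ± 152 CPM, a log2 fold change of -1.67 ± 0.17 (edgeR adjusted p = 0.0045). Its co-chaperone Dnajb1 changed by -1.33 ± 0.10 (edgeR adjusted p = 0.00118). Stip1, Dnaja1 and Hsph1, which assist HSC70 or HSP90, made up the rest. With the block 10 members fell. The camera adjusted p was 1.3e-08, and the adjusted p was 0.35 with an estimated correlation.

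**Figure D3:**
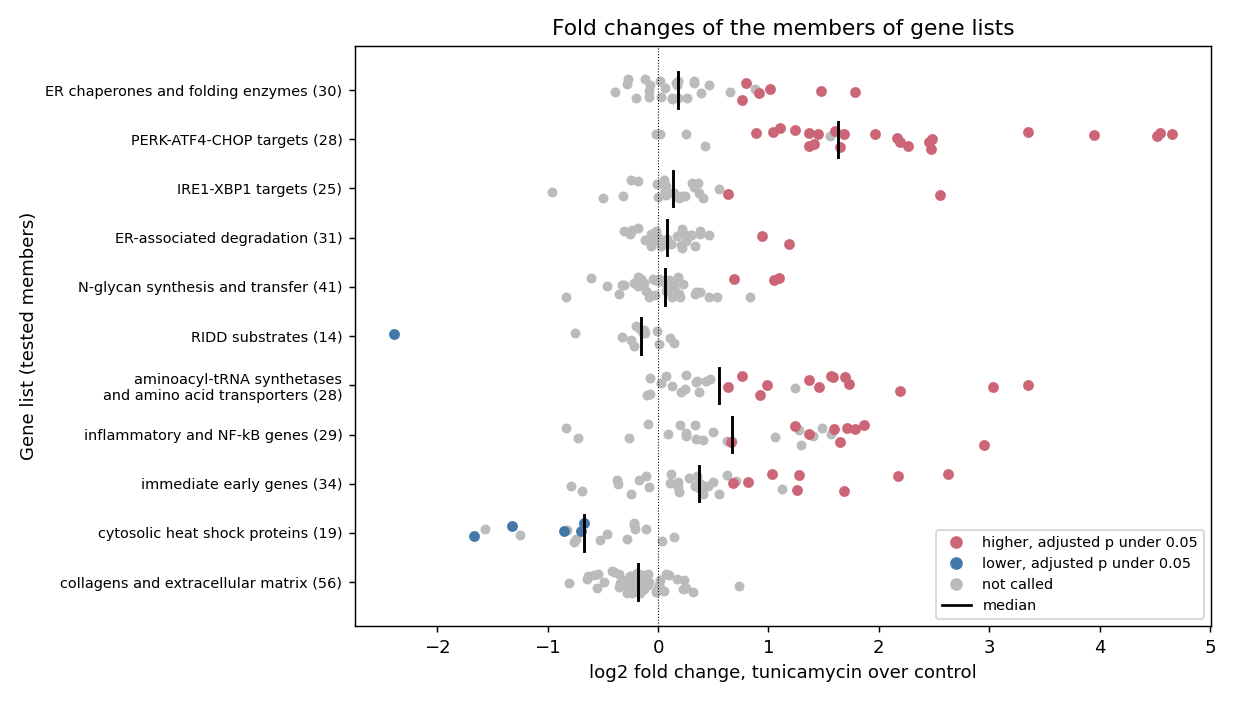
Log2 fold change of tunicamycin over control (horizontal axis) of each tested member of 11 gene lists (vertical axis, number of members in brackets). Red points rose and blue points fell at an adjusted p under 0.05, grey points were not called and bars are medians, which run from 1.63 for PERK-ATF4-CHOP targets to -0.67 for cytosolic heat shock proteins.

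Among 56 collagens and matrix genes 0 rose and 0 fell in edgeR, also when adjusted over the list alone. In the fit with the replicate block 6 were lower, DESeq2 called 0 higher and 3 lower, limma-voom called 0, and at an unadjusted edgeR p under 0.05 there were 1 higher and 4 lower. Animals differed in matrix genes of cartilage, with Col2a1 at 742 to 842 CPM in animal BW35770 and 4094 to 6258 CPM in the others. The median log2 fold change of the matrix list was -0.18, and ran from -0.33 to -0.016 with libraries or animals left out. Emilin1, an elastic fibre glycoprotein, had a log2 fold change of -0.64 ± 0.13 (edgeR adjusted p = 0.0541, and 0.0193 with the block). Mmp14, a membrane-bound collagenase, had -0.54 ± 0.12 (edgeR adjusted p = 0.0625, and 0.0397 with the block). DESeq2 called both lower (adjusted p = 0.00098 and 0.002). Camera called the list lower (adjusted p = 0.04), with an adjusted p = 0.76 with an estimated correlation and 0.51 with fry, and the call was lost without the tunicamycin library of BW35770 or BW35773 or the control of BW35772 or BW35773 (adjusted p = 0.22, 0.33, 0.16 and 0.22). In SRF-YAP and TGF-beta responsive genes, which serve contraction and growth, 1 of 25 rose and 0 fell (1 and 3 adjusted over the list alone), and the median was -0.24. The gene that rose was Lats2, a kinase that inhibits YAP, at 0.58 ± 0.12, and Tpm1, a tropomyosin, had -0.65 ± 0.13 (edgeR adjusted p = 0.0534, 0.0215 with the block, and 0.00039 in DESeq2). With the replicate block 2 rose and 2 fell, Nuak2, Tpm1 and Smad7 being added to Lats2. This list was called lower (camera adjusted p = 0.025), with an adjusted p = 0.46 with an estimated correlation, 0.1 with fry, 0.051 in camera under the stricter filter and 0.29 in camera without the tunicamycin library of animal BW35773. Lats2 lost its call without the control of BW35770, BW35772 or BW35773 (edgeR adjusted p = 0.15, 0.22 and 0.24) or the tunicamycin library of BW35770 or BW35772 (0.16 and 0.083), with no filter (0.056) and in limma-voom (0.054). These fits did not pair the animals. Pairing by the replicate block over all libraries gave edgeR adjusted p = 0.0334. Without animal BW35770 or BW35772 the blocked values were 0.38 and 0.081.

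Mitochondrial electron transport genes were called lower in camera (adjusted p = 0.04) at a median log2 fold change of -0.08, with 0 of 31 members called in edgeR, DESeq2 or limma-voom without the block (also adjusted over the list alone, and 3 lower at an unadjusted edgeR p under 0.05) and an adjusted p = 0.94 with an estimated correlation. That call was lost without either library of animal BW35770, the treated library of BW35772 or the control of BW35773 (adjusted p = 0.22, 0.087, 0.96 and 0.082). It was also lost with fry (0.63), with DESeq2 (0.087) and with the exon length trend removed, where the median was -0.036 (0.25, and 0.3 with the replicate block). Sdhc and Sdhd, subunits of succinate dehydrogenase, had log2 fold changes of -0.54 ± 0.17 and -0.39 ± 0.12. Sdhc was called lower with DESeq2 and the replicate block (adjusted p = 0.0075), with the length trend removed and the block (0.017), and in edgeR without the tunicamycin library of BW35773 (0.027). Cytosolic ribosomal proteins had 0 of 33 members called in edgeR, DESeq2 or limma-voom, 0 adjusted over the list alone and 0 at an unadjusted edgeR p under 0.05. Rpl7 and Rpl15 had log2 fold changes of -0.15 ± 0.20 and -0.15 ± 0.18. Their list had a camera adjusted p = 0.54, but was called higher without the treated library of BW35772 (adjusted p = 0.0089) and lower without that of BW35773 (4.6e-05). Differences between treatments followed exon length in opposite ways between animals. In the shortest sixth of tested genes, up to 962 bases, the median log2 difference was -0.29 in animal BW35770, -0.44 in BW35772 and 0.16 in BW35773. In the longest sixth, from 4077 bases, it was 0.13, 0.18 and -0.19.

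Pathways without a list call had few changed members. Cell death regulators had 3 of 26 higher and 0 lower (4 and 1 adjusted over the list alone). These were Birc3, an inhibitor of apoptosis, at a log2 fold change of 2.11 ± 0.15, Casp8, an initiator caspase, at 1.85 ± 0.19, and Bbc3, the pro-apoptotic PUMA. The cell cycle inhibitor Cdkn1a, 1 member, was lower with the replicate block. In vesicle transport between ER and Golgi 2 of 47 rose and 0 fell (3 and 0 adjusted over the list alone), namely Stx5a, a Golgi syntaxin, at 1.03 ± 0.10 and Sec23b, and the replicate block added Arfgap3 to make 3 higher. The median of that list was -0.01, its mean 0.07 and its camera direction up. Among 23 NRF2 and oxidative stress genes Slc7a11 rose and 0 fell (1 and 0 adjusted over the list alone), and with the replicate block 2 rose and 1 (Hmox1) fell. Osgin1, an NRF2 target, had a log2 fold change of 1.22 ± 0.32 (edgeR adjusted p = 0.113, 0.00486 with the block, and 0.0039 in DESeq2). The median of the NRF2 list was -0.09 and its mean 0.09, with a camera direction of down. Of 28 autophagy genes Atg12, a ubiquitin-like conjugation protein, rose by 0.70 ± 0.12, and of 37 sterol and fatty acid genes Mvd, an enzyme of cholesterol synthesis, rose by 0.90 ± 0.16, with 0 lower in either list in edgeR and the same counts adjusted over the list alone. DESeq2 called 1 autophagy gene lower. Map1lc3b, the autophagosome protein LC3B, had a log2 fold change of -0.44 ± 0.11 and Insig2, a brake on sterol synthesis, of -0.50 ± 0.15, neither of them called in edgeR. Map1lc3b was called with DESeq2 (adjusted p = 0.0074, and 0.026 with the replicate block) and Insig2 with DESeq2 and the replicate block (0.012). Calls were lost for Atg12 without the control of BW35770, BW35772 or BW35773 (edgeR adjusted p = 0.13, 0.16 and 0.14) or the tunicamycin library of BW35772 (0.064). That for Mvd was lost without the same controls (0.12, 0.16 and 0.16) or the tunicamycin library of BW35770 (0.12). These fits did not pair the animals. Pairing by the replicate block over all libraries gave edgeR adjusted p = 0.0164 for Atg12 and for Mvd. Without animal BW35770 the blocked values were 0.18 and 0.24. Cell cycle and mitosis had 0 of 48 members called in edgeR, also when adjusted over the list alone, with 1 higher in DESeq2, 0 in limma-voom and 1 higher at an unadjusted edgeR p under 0.05. Mcm7, a replication helicase subunit, had a log2 fold change of 0.44 ± 0.13 and Ccne1, cyclin E1, of -0.56 ± 0.27, neither of them called in edgeR. Mcm7 was called higher with DESeq2 (adjusted p = 0.039, and 0.031 with the replicate block), and with the length trend removed and the block Mcm7 was called higher (0.036) and Ccne1 lower (0.037). Camera adjusted p-values were 0.071 for cell death, 0.54 for vesicle transport and for sterol synthesis, 0.87 for NRF2 and autophagy, and 0.94 for the cell cycle. The cell cycle list was called lower without the control of animal BW35770 (adjusted p = 0.00037) and higher without its tunicamycin library (0.047).

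Markers of cell types showed the makeup of the cultures. Vim, vimentin, stood at 7492 to 9760 CPM in the 6 libraries, and Col1a1 at 1107 to 3569 CPM. Cartilage genes were also abundant, with Col2a1, the main collagen of cartilage, at 742 and 842 CPM in the control and treated library of animal BW35770 and at 4094 to 6258 CPM in the other animals' libraries. Acan, the cartilage proteoglycan aggrecan, stood at 836 to 2112 CPM. Thy1, a fibroblast surface marker, stood at 752 and 827 CPM in animal BW35770 and at 58.0 to 118.0 CPM in the others. Between treatments 0 of 12 tested chondrocyte markers and 0 of 14 fibroblast markers were called, with medians of -0.07 and -0.15 (camera adjusted p = 0.97 and 0.22). At an unadjusted edgeR p under 0.05 there were 1 chondrocyte and 1 fibroblast marker lower. Adjusted over the list alone, 0 chondrocyte markers were called and 1 fibroblast marker, Prrx1, was lower, as it was with DESeq2 and the replicate block. Krt5, Krt1, Ptprc and Cdh5, markers of keratinocytes, leukocytes and endothelium, stayed below 0.1 CPM in every library. Other members of these lists were present, with Krt14 at 2.23 to 22.7, Itga6 at 17.6 to 32.8, Eng at 95.0 to 206.7 and Cd68 at 68.6 to 175.2 CPM. Of the tested members, 0 of 5 keratinocyte, 0 of 6 Schwann cell and melanocyte, 0 of 9 muscle and 0 of 7 adipocyte markers were called (edgeR, with camera adjusted p = 0.26, 0.89, 0.16 and 0.87), and 0 adjusted over the list alone. DESeq2 called 1 muscle marker lower, limma-voom called 0 of these markers, and 1 muscle and 1 Schwann cell marker were lower at an unadjusted edgeR p under 0.05. The endothelial and leukocyte lists had 4 tested members each, too few for a list test, and 0 of them were called in edgeR, DESeq2 or limma-voom or had an unadjusted edgeR p under 0.05. In the blocked edgeR fit adjusted over the list alone, 2 leukocyte and 0 endothelial markers were lower. With the replicate block the muscle list was called lower (camera adjusted p = 0.047, and adjusted p = 0.61 with an estimated correlation), with Lmod1 lower, and Krt14 of the keratinocyte and S100b of the Schwann cell list were called lower. The median of the Schwann cell and melanocyte list was -0.19 and its camera direction up.

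**Figure D4:**
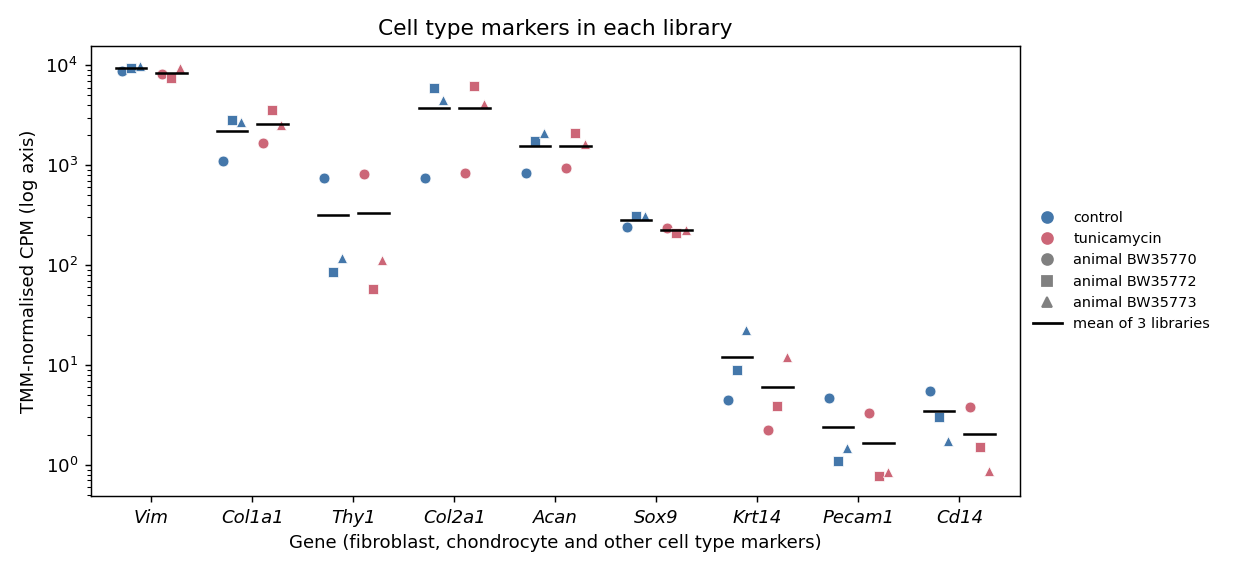
TMM-normalised CPM on a log axis (vertical) of marker genes of fibroblasts (Vim, Col1a1, Thy1), chondrocytes (Col2a1, Acan, Sox9) and other cells (Krt14, Pecam1, Cd14) in each library, with symbols for animals, colours for treatment and bars for the mean of 3 libraries. Col2a1 and Thy1 differ between animal BW35770 and the others in both treatments.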

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

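Removal of the exon length trend was chosen after seeing the data, and the other alternatives were planned. With the replicate block 415 genes rose and 324 fell, with DESeq2 676 and 401, with DESeq2 and the replicate block 709 and 622, and with a fold change of 1.5 as the null 57 and 18. Removal of the exon length trend gave 298 and 190, and 724 and 749 with the replicate block as well. DESeq2 size factors, upper-quartile factors, both other filters and limma-voom gave 218 to 287 and 103 to 129. The blocked fit held all 241 and 107 genes, and the block changed no call of a list or named gene beyond those printed with the results. Across the fits that left out a library or an animal, genes that rose numbered 20 to 806 and genes that fell 3 to 826, with both extremes without animal BW35773 (20 and 3 without the block, 806 and 826 with it). Fits without an animal rest on 2 pairs. Of the 37 named genes called, 37 kept their call with DESeq2, with the block and with the length trend removed, 34 with limma-voom (Sec23b, Slc7a11 and Lats2 lost), 36 with upper-quartile factors (Sel1l lost) and 36 with no filter (Lats2 lost). Leaving out a single library kept 23 to 32 of them, leaving out both libraries of BW35770, BW35772 or BW35773 kept 20, 17 and 10 (26, 36 and 37 with the block), and 0 reversed.

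Median log2 fold changes do not depend on the list test, so only the calls moved there. With an estimated correlation the ER chaperones (0.18), PERK-ATF4-CHOP targets (1.63), IRE1-XBP1 targets (0.13) and ER-associated degradation (0.079) lost their calls, and fry lost these except PERK-ATF4-CHOP. Fry also lost matrix, SRF-YAP and electron transport genes. Under the stricter filter SRF-YAP genes (-0.22, adjusted p = 0.051, range over alternatives 0.0046 to 0.46), IRE1-XBP1 targets (0.15, adjusted p = 0.056, range over alternatives 0.0071 to 0.61) and ER-associated degradation (0.089, adjusted p = 0.051, range 0.013 to 0.5) were no longer called. RIDD substrates became called lower with the replicate block (-0.15), DESeq2 (-0.14), DESeq2 with the replicate block (-0.14), limma-voom (-0.16), fry (-0.15), and the exon length trend removed without (-0.16) and with the replicate block (-0.16), and without both libraries of BW35770 (-0.15, adjusted p = 0.049). Their adjusted p ranged from 0.0015 to 0.37, and was 0.61 with an estimated correlation and the replicate block. The cause was not tested. PERK-ATF4-CHOP targets were not called with an estimated correlation, without or with the replicate block, and were called in the other settings, with medians from 1.58 to 1.80. N-glycan genes were called in none. Electron transport genes lost their call with DESeq2 (-0.070, adjusted p = 0.087) and with the exon length trend removed (-0.036, 0.25, and -0.046, 0.3, with the replicate block), over a range of 9.4e-06 to 0.96. Cell death regulators were called higher with no filter, DESeq2 with and without the block, and fry (adjusted p from 0.0058 to 0.46 over alternatives).

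With libraries or animals left out, medians ranged from 0.10 to 0.29 for ER chaperones, 0.091 to 0.18 for IRE1-XBP1 targets, 0.028 to 0.16 for ER-associated degradation and -0.16 to -0.076 for RIDD substrates. Directions turned in some of these fits for vesicle transport (-0.02 to 0.047), NRF2 genes (-0.20 to 0.06), autophagy (-0.048 to 0.10), cell cycle (-0.27 to 0.13), ribosomal proteins (-0.27 to 0.21), electron transport (-0.27 to 0.06), chondrocyte markers (-0.55 to 0.45), Schwann cell and melanocyte markers (-0.50 to 0.11), adipocyte markers (-0.75 to 0.32) and Rpl7 (-0.36 to 0.024).

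Other turns, of the direction given by the list test, were in lists that were not called in either fit, with 1 exception. NRF2 genes turned with the replicate block (-0.093), DESeq2 with the replicate block (-0.082) and the length trend removed with the replicate block (0.023). Chondrocyte markers turned with the replicate block (0.019) and no filter (-0.062). Schwann cell and melanocyte markers turned with the replicate block (-0.22), no filter (-0.11), DESeq2 (-0.18), DESeq2 with the replicate block (-0.19), limma-voom (-0.16) and the length trend removed with the replicate block (-0.24). Cell cycle genes turned with limma-voom (0). The exception was ribosomal proteins, which were called higher with the exon length trend removed (0.13, adjusted p = 0.042, and 0.12 with the replicate block, adjusted p = 0.017, range over alternatives 4.6e-05 to 0.99). The cause of the other turns was not tested. Depth was not varied, so what it limits was not tested.

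Of the 10 splits of the 6 libraries into 3 and 3, the real one gave 348 called genes and the highest other 0, so 1 split, the real one, was as large. Of the 4 splits that part all 3 animals, analysed with the block, the real one gave 739 and the highest other 0, again 1, the real one. The splits are too few for a share under 0.05.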

Other observations

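The tests of AHR and BMP targets, of Cyp1a2 reads, of cell type markers and of immediate early genes below were chosen after the values or related values had been seen, while the effect of removing the length trend had not been seen. Genes that fell included further regulators known to respond to bone morphogenetic proteins (BMPs). Beside Id1 and Id2, Id3 had a log2 fold change of -1.53 ± 0.28 and Smad6, an inhibitor of BMP signalling, -1.34 ± 0.11 (SE, edgeR adjusted p = 0.0371 and 0.00137, n = 3 animals). Hey1 fell by 1.90, Dlx5 by 1.20 and Dlx3 by 1.32 on the log2 scale. Beside Cyp1a1, Ahrr, the repressor of the aryl hydrocarbon receptor (AHR), rose by 1.88 ± 0.32 and Cyp1b1 by 1.37 ± 0.27 (edgeR adjusted p = 0.0298 and 0.0473). These genes went the same way in all 3 pairs, and Id1, Id2, Id3, Smad6, Cyp1a1, Ahrr and Cyp1b1 were also called with the exon length trend removed.

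The rise of Cyp1a1, Ahrr and Cyp1b1 is considered first. For Cyp1a1, treated libraries held 390 times as many counts as for its paralog Cyp1a2, which argues against reads shared with Cyp1a2 as the source of its rise. The ratio is of counts as assigned, and how shared reads were assigned is not given. It does not bear on Ahrr or Cyp1b1. A candidate explanation is activation of the aryl hydrocarbon receptor. Of 6 other target genes tested 5 had positive log2 fold changes, with a median of 0.65, but 0 were called without the block and 2 with it (Aldh3a1 and Cyp1a2). Cyp1a2 is not independent evidence, since it held 114 counts over the treated libraries against 44411 for Cyp1a1. Whether reads shared with Cyp1a1 account for the rise of Cyp1a2 was not tested. The values of 5 of the 6 targets had been seen before their list was written. The remaining gene, Cyp2s1, had 0.38, so receptor activation stays open, as does whether the compound or its vehicle would be the cause.

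The fall of Id1, Id2, Id3 and Smad6 was set against cartilage markers, of which 0 of 12 were called in edgeR and 1 was lower at an unadjusted p under 0.05. Their median log2 fold change was 0.02 with the replicate block (quartiles -0.16 and 0.06, 12 genes). It ran from -0.55 to 0.45 with libraries or animals left out, mostly in fits that did not pair the animals. The markers moved together (estimated correlation 0.562), so the quartiles are not a measure of error. These values argue against a lower share of chondrocyte-like cells as the source of falls of this size, and leave a smaller change open. A loss of short-lived transcripts in general stays open, since immediate early genes had a median of 0.37 but went both ways (26 of 34 positive, Jun and Dusp1 lower with the replicate block), and stress can induce them. Lower BMP-SMAD signalling may be involved and also stays open. Of 13 other target genes 11 had negative values, the median of all 13 was -0.88, and 3 were called lower without the block and 8 with it. Those 3 are Hey1, Dlx5 and Dlx3, named above, and the 8 are the genes whose values had been seen before the list was written. These calls are therefore not independent evidence. The 5 not seen had a median of -0.01 (from -0.88 to 0.46) and were not called in either fit.

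Over all 13503 tested genes the log2 differences of animal BW35773 were the least like those of the others. In called genes, chosen from these same libraries, their size was similar. Median rises were 1.02, 1.04 and 1.12 and median falls -1.04, -1.08 and -1.02 in BW35770, BW35772 and BW35773. The rest of this paragraph concerns all tested genes of animal BW35773. Across genes, which are not independent replicates, its log2 differences correlated with those of the other animals at a mean r of 0.23, against 0.56 between those animals. With the exon length trend removed these values were 0.30 and 0.52. Unequal recovery of long and short transcripts may therefore contribute (13.8% of the variance of its deviation). The gap left after removal does not decide whether it is the whole cause. Annotated exon bases may differ from the length of the transcripts in these cells, so the trend may have been removed only in part. Of the keratinocyte, endothelial, leukocyte, and Schwann cell and melanocyte markers, 38 were under 1 CPM in the other 5 libraries. The highest of them in the treated library of BW35773 (Krt10) stood at 0.87 CPM, which argues against those cell types having been gained there. It says nothing of other cell types, of cells lost, or of markers expressed in all libraries, such as Krt14 and Itga6. A response that differs between animals cannot be told apart from chance in a culture, because there is 1 pair per animal.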
